A study of Mus musculus with 6 samples.

How the data were processed

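Total RNA of dispersed mouse islet cells, cultured for 72 h without (control) or with 50 µg/ml of T lymphocyte exosomes (exoNOD), was labelled with Cy3 and hybridised to 1-colour Agilent mouse gene expression arrays, 3 per group. The deposited array files hold, per the file headers, the output of Agilent Feature Extraction 11.0.1.1. Its processed signal is an intensity, background-subtracted and spatially detrended within the array by the authors' software and not normalized between arrays. The deposited spot flags (other values, 0 or 1, per the file headers) give whether a spot is well above background, saturated or uneven. The authors' processed values are on the log2 scale. They cover 31766 of 39429 probes, of which 31755 were above background on at least 3 arrays, and they lie close to a quantile normalization of the processed signal (median absolute difference between 0.0019 and 0.0032). The values of each sample correlated across probes most with its own array (r of at least 0.9998); probes are not independent replicates.

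The processed signal was taken as log2, spots of a probe were averaged, and the 75th percentile of each array over non-control spots was subtracted. Probes were kept if well above background on all arrays of at least 1 group (31065 probes). Gene symbols came from RefSeq accessions; 27234 probes had a symbol and 12195 did not and were kept under their own name. The probe with the highest mean stood for its gene, giving 25780 genes, 17252 of them under a symbol. No genome positions were used. For the 111 genes above background on all arrays of 1 group and on no array of the other, the fold change is given as a lower bound. All arrays had a similar 75th percentile of signal, between 812 and 890, and between 0.381% and 0.618% of spots marked uneven. The median signal was lower on control arrays (112 to 117) than on exoNOD arrays (121 to 140). The number of arrays sets the precision.

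Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend), with data.table (version 1.17.8) for reading files, and Benjamini-Hochberg adjustment over all genes, threshold 0.05. Lists were tested with camera in limma, two-sided, with a preset inter-gene correlation of 0.01 and adjustment over 28 lists; the median change of each list was also ranked among 10000 random lists of equal brightness; 550 of their 601 genes were tested. The lists were chemokines, study chemokines, NF-kB and cytokine response, interferon-stimulated genes, MHC class I antigen presentation, complement and acute phase, apoptosis regulators, p53 targets, unfolded protein response, oxidative stress response, immediate early and heat shock, hypoxia and glycolysis, sterol and fatty acid synthesis, oxidative phosphorylation, cell cycle, reported miR-155 targets, beta cell identity, stimulus-secretion coupling, beta cell disallowed genes, and markers of alpha, delta and PP cells, acinar, duct and endothelial cells, fibroblasts with stellate cells and pericytes, macrophages with dendritic cells, T lymphocytes, B lymphocytes, and Schwann cells with neurons. The tests, the lists, the rule for named genes and most of the other settings were fixed before the data were examined.

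Genes were named by rule among those with an established symbol. The rule takes up to 12 rises and 12 falls with the greatest change among genes past the threshold with the same sign in all 3 pairs of equal replicate number, filled to 12 by lowest unadjusted p with genes that did not pass. It also takes the 4 members of each list with the lowest unadjusted p, and always Ccl2, Ccl7, Cxcl10 and the islet hormone genes; members of lists that did not pass may be left out. Some genes that the rule takes are not reported here. Genes outside the rule are given as chosen after their values were seen.

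The labels do not say that equal replicate numbers share an islet preparation. Across genes, deviations from the group mean correlated at 0.366, 0.280 and 0.481 between arrays of equal number and between −0.341 and 0.0088 otherwise. The values for equal numbers lie above the 0.1 set for each pair, so equal numbers were taken as pairs. They do not establish the pairing, since so few arrays can be matched in only a few ways. Deviations within a group also cancel out, so high values for some matches lower the others. Genes are not independent replicates. The planned test has no block for the pairs, and values with the replicate number as a block in limma are given beside it. Slide was inferred from the scan times, taking 1 slide per scan. This places the controls and exoNOD replicate 1 on 1 slide and the other exoNOD arrays on a second, so slide was also used as a block. The second slide holds no control, so the group difference of that fit comes from exoNOD replicate 1 alone and the other exoNOD arrays add only to its error.

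The other settings fixed then were the replicate block, normexp background correction with an offset of 50, quantile normalization, scaling by the median, the authors' values, no background filter, a filter on all 6 arrays, eBayes without trend or with robust estimation, array weights, slide as a block, each replicate number or array left out, the mean of a gene's probes, all probes separately, camera with an estimated correlation, fry, an adjusted p under 0.1, and an unadjusted p with a 1.5-fold change. Normexp was meant for mean spot signals, which were not used here, and took median spot signals. Settings chosen after seeing the data were the comparison within slide 1, the replicate block combined with quantile normalization, with the authors' values, with normexp or without a pair, and 2 other normexp fits: the RMA-75 estimate, and spots with a local background over 100 given the median background of their array. Genes with microRNA seed sites were not analysed here, since 3′ UTR sequences were not used here.

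The procedure was tested on simulated data with 6 arrays and 25780 genes. Without the block it recovered 10% of rises of 1.5-fold, 52% of rises of 2-fold, 88% of rises of 4-fold and 52% of falls of 2-fold, and called 0.0078% of unchanged genes. With the replicate block these shares were 14%, 42%, 78%, 38% and 0.0039%. The arrays simulated for the block held a true pair effect, and neither set held a slide effect or a brightness-dependent shift. The shares therefore hold only under those conditions. Camera found a chemokine list raised by 1.52-fold and 0 of 25 unchanged lists in both fits. The simulated genes varied independently of one another, whereas the correlation estimated in the data lay between −0.043 and 0.929 per list. The simulation therefore does not show how often camera calls an unchanged list of correlated genes.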

Results

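Gene expression was measured in dispersed pancreatic islet cells of male C57Bl/6N mice after 72 h of culture. Control cells received no exosomes (3 arrays). The exoNOD cells received 50 µg/ml of exosomes, small vesicles released by cells, from CD4+CD25- T lymphocytes of NOD mice, a strain that develops autoimmune diabetes (3 arrays). The 3 experiments used different islet and exosome preparations. Every array held 43020 spots for transcripts. Between 78.1% and 81.8% of these spots were well above background, the median signal per array lay between 112 and 140, and 0 spots were saturated. Levels are log2 signals relative to the 75th percentile of their array, and changes are exoNOD minus control with n = 3 arrays per group. The number of arrays limits the precision.

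The cells carried abundant hormone transcripts in both groups. Ins2, which encodes insulin, had a level of 8.70 ± 0.05 (SD, n = 3) in control and 8.63 ± 0.02 in exoNOD cells. Gcg, which encodes glucagon, had 8.68 ± 0.04 and 8.58 ± 0.01, and the amyloid peptide gene Iapp 8.27 ± 0.08 and 8.26 ± 0.03. These levels lay near the top of the signal range. The highest signal per array was between 365857 and 406730, against 75th percentiles between 812 and 890. Whether the arrays could show a change at such levels was not tested. The log2 changes were −0.12 for Ins1 (limma adjusted p = 0.498), −0.07 for Ins2 (0.713), −0.10 for Gcg (0.579), −0.21 for the somatostatin gene Sst (0.460), −0.35 for the pancreatic polypeptide gene Ppy (0.280) and −0.01 for Iapp (0.949), so none of these genes passed. The change of Ins2 was positive after quantile normalization (0.033) and in the authors' values (0.025), as was that of Gcg in the authors' values (0.025) and that of Iapp in exoNOD replicate 1 against the controls of its slide (0.017). With the replicate block Ppy had an adjusted p of 0.0726. It passed with the block after quantile normalization (log2 change −0.39, adjusted p = 0.0196) and in the authors' values with the block (−0.39, 0.0256).

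The first principal component held 49.8% of the variance between arrays and placed the control arrays at −39.6, −34.2 and −7.04 and the exoNOD arrays at −1.58, 38.2 and 44.2 (replicates 1, 2 and 3). By their scan times, the controls and exoNOD replicate 1 lay on 1 slide, and exoNOD replicates 2 and 3 on another.

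**Figure D1:**
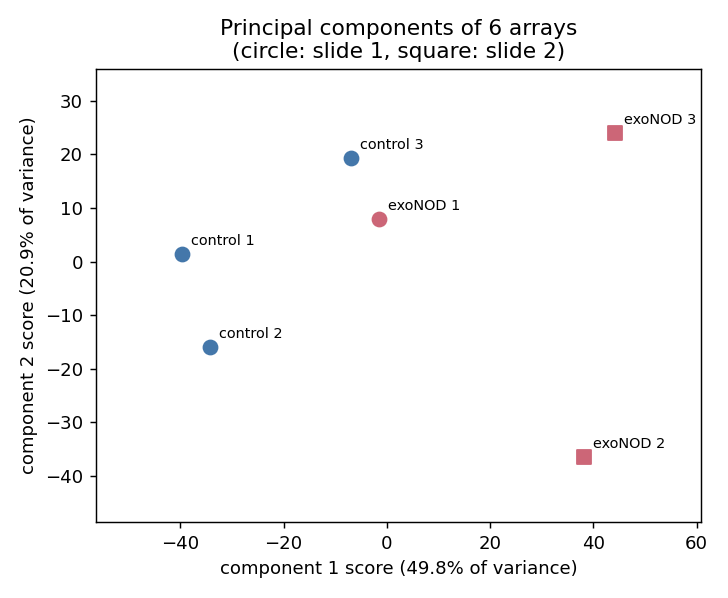
Scores of the 6 arrays on the first principal component (horizontal axis, 49.8% of the variance) and on the second (vertical axis, 20.9%), blue for control and red for exoNOD, circles for slide 1 and squares for slide 2. The exoNOD arrays on slide 2 lie at 38.2 and 44.2 on the first component, and exoNOD replicate 1, on the slide of the controls, at −1.58.

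The comparison of exoNOD with control cells asks how exosomes from T lymphocytes of diabetes-prone mice alter the gene expression of islet cells. Vcam1, an adhesion molecule that binds leukocytes, rose 2.16-fold (log2 change 1.11 ± 0.13 SE, limma adjusted p = 0.0363), and the hyaluronan synthase gene Has2 rose 2.17-fold (1.11 ± 0.13, 0.0287). Chil3, a chitinase-like protein of activated macrophages, rose 2.75-fold (1.46 ± 0.16, 0.0287), and the mast cell tryptase gene Tpsb2 rose 2.45-fold (1.30 ± 0.14, 0.0287). Cdh11, a cadherin of mesenchymal cells, rose 2.13-fold (1.09 ± 0.14, 0.0454). Apoe, which encodes the lipid carrier apolipoprotein E, fell by 1.17 ± 0.12 on the log2 scale, with 2.25-fold more signal in control than in exoNOD cells (adjusted p = 0.0287).

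Further rises were those of Apol7c, of the apolipoprotein L family (log2 change 1.83 ± 0.23, adjusted p = 0.0417), Rnase10, of the ribonuclease A family (1.64 ± 0.17, 0.0287), and Adamts14, a procollagen-processing protease (1.34 ± 0.17, 0.0454). Ldhc, a lactate dehydrogenase of the testis, was above background on all 3 exoNOD arrays and on 0 control arrays and was at least 2.28-fold higher in exoNOD cells (adjusted p = 0.0484). In all, 27 of 25780 genes passed, of which 26 rose and 1 fell. Of the 27, 17 carry only a probe or clone name or a provisional symbol. All 27 moved the same way in each of the 3 pairs of equal replicate number, as did 51.2% of all tested genes; the arrays that show this are those that made the calls.

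The next genes by p did not pass. Among the rises these were H2-Eb2, an MHC class II gene (log2 change 1.5, adjusted p = 0.0551), the cholecystokinin gene Cck (1.54, 0.0599) and Fscn3 (1.08, 0.0599). The falls not past the threshold were Fgf23, Marchf1, Slc8a3, Fbxo31, Krt222, Slc17a5, Mcidas, Oacyl, Tacr2, Idua and Fam107a, with log2 changes between −0.68 and −0.55 and adjusted p between 0.0599 and 0.0701. All of these passed with the replicate block, where Fgf23 had an adjusted p of 0.0028, Marchf1 0.00215 and Cck 0.00147.

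The replicate block assumes that equal replicate numbers are pairs, which the labels do not state. Once it was added, 2256 genes passed, of which 1784 rose and 472 fell. They contain the 27 genes, 359 rose and 20 fell by at least 2-fold, and 96.9% of them moved the same way in exoNOD replicate 1 against the controls of its slide, as did 74.4% of all tested genes with their group difference. That array is among those that made the calls. It lay beyond all 3 controls in the direction of the call for 74.2% of the 2256 genes, and beyond them in either direction for 48.1% of all tested genes, and 85.3% of the 2256 differed more from the controls on slide 2 than on slide 1. Slide 2 holds no control, so a fit with slide as a block sets exoNOD replicate 1 alone against the 3 controls, without the pairing, and assumes that this lone array varies like the others. Its camera p for a list reflects how far the genes of 1 array moved alike, not replication. For lists the mean difference on slide 1 is therefore given. It is taken from the mean of the 3 controls, so a single control can lie beyond exoNOD replicate 1. In that fit 0 genes passed in limma (929 at an unadjusted p under 0.05), and 0 passed in slide 1 alone (1143). At an unadjusted p under 0.05 there were 4289 genes, 79.7% of them higher in exoNOD cells. This share was 57.8% after quantile normalization, where 20 genes rose and 12 fell, 57.4% in the authors' values, where 18 rose and 13 fell, and 41.8% after scaling by the median, which moved the median change of all genes from 0.035 to −0.11 and left 12 rises and 1 fall. With the block, 819 rose and 377 fell after quantile normalization, and 864 rose and 393 fell in the authors' values. The share of rises at an unadjusted p under 0.05 was 69.1% with the block. It was 50.1% with the block after quantile normalization and 50.1% with the block in the authors' values.

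Single arrays moved the count of 27. Limma called 0 genes without control replicate 1 (2555 at an unadjusted p under 0.05), 0 without control replicate 2 (2420) and 0 without exoNOD replicate 2 (3050), 2 without exoNOD replicate 3, 75 without control replicate 3, and 1269 without exoNOD replicate 1, which leaves each group on its own slide. With the block the count was 4162 without pair 1, 431 without pair 2 and 1729 without pair 3.

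**Figure D2:**
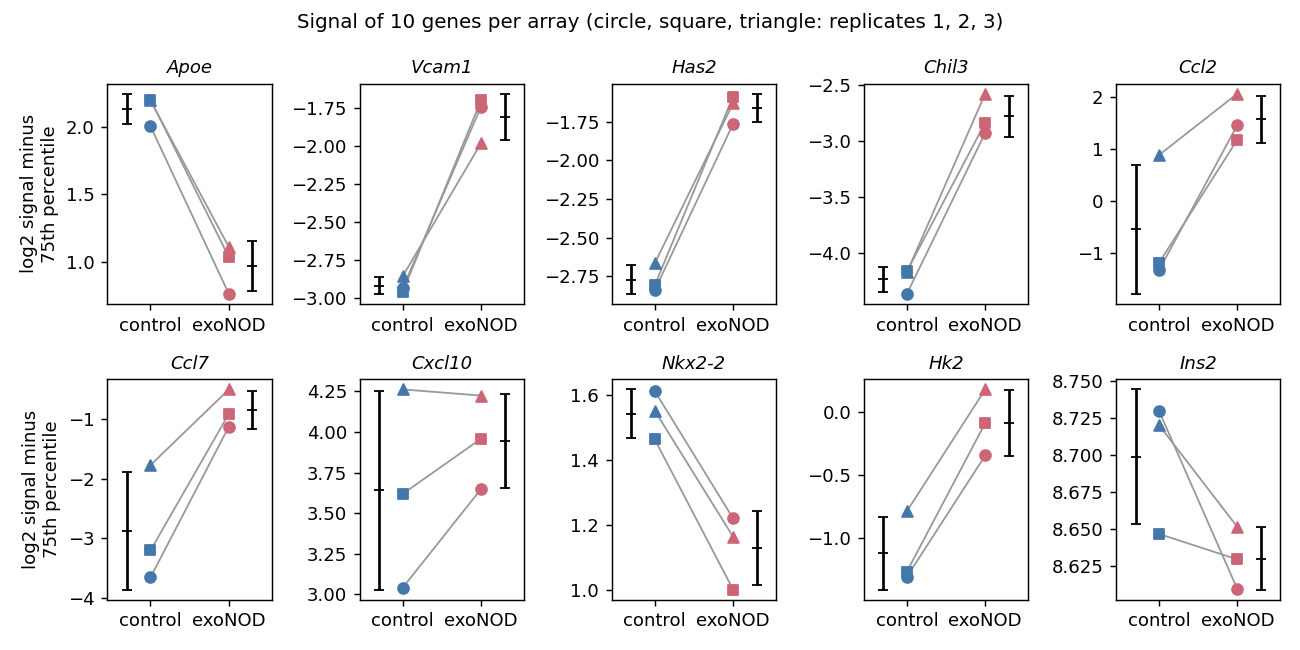
Level of 10 genes on each array (vertical axes, log2 signal minus the 75th percentile of the array, a different range in each panel), with lines joining arrays of equal replicate number and black bars for the mean ± SD of 3 arrays. Apoe falls by 1.17 between the means and Vcam1 rises by 1.11; the control arrays of Ccl2 spread with an SD of 1.23, and Ins2 differs by −0.07.

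Chemokines, the signals that draw leukocytes into tissue, were higher in exoNOD cells as a list (mean log2 change 0.92, 17 of 20 tested members higher, camera adjusted p = 0.0045). The call was lost with adjusted p = 0.438 with an estimated correlation. The neutrophil attractant Cxcl5 had the greatest change of the 4 members with the lowest p (8.48-fold, log2 change 3.08 ± 0.77, limma adjusted p = 0.152, 7.13e-05 with the replicate block), and Ccl4 changed by 0.49 ± 0.10 (0.0878, 0.0128 with the block). Over all genes 0 members passed, and 7 passed adjusted over the list alone. Under the replicate block 8 rose, 2 fell and 10 did not pass, and 15 passed adjusted over the list alone. The falls, named after their values were seen, were Cxcl12 (−0.68, 0.0166) and the fractalkine gene Cx3cl1 (−0.44, 0.0193). On slide 1 the list mean of exoNOD replicate 1 lay 0.69 above the mean of the 3 controls. It lay 1.02 above control replicate 1 and 0.055 above the highest control. The other pairs differed by 1.27 and 0.47.

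The chemokines Ccl2, Ccl7 and Cxcl10 are known from the study itself, so their direction is not independent evidence. Ccl2, a monocyte attractant, had 4.30 times the control signal in exoNOD cells (log2 change 2.11 ± 0.52, adjusted p = 0.150, 0.00132 with the replicate block). Ccl7, its close relative, had 4.10 times the control signal (2.03 ± 0.42, 0.0924, 0.00082 with the block). Cxcl10, an attractant of activated T lymphocytes, changed by 0.30 ± 0.28 (0.595, 0.127 with the block) and by 0.0081 in exoNOD replicate 1 against the controls of its slide. As a list the 3 genes rose (mean 1.48, camera adjusted p = 0.016; adjusted p = 0.475 with an estimated correlation). Over all genes 0 of them passed and 2 passed adjusted over the list alone; with the block 2 rose and 1 did not pass. The mean of exoNOD replicate 1 lay 1.25 above the 3 controls and 1.98 above control replicate 1. The list did not pass without exoNOD replicate 1 (mean 1.60, 0.0714).

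Genes of the NF-kB and cytokine response rose as a list (mean 0.53, 24 of 25 higher, camera adjusted p = 0.000628; adjusted p = 0.558 with an estimated correlation). Vcam1 passed over all genes, and 3 members passed adjusted over the list alone. In the fit with the replicate block 11 rose and 14 did not pass. Among those 11 were Ptgs2, the inducible cyclooxygenase (log2 change 1.51, adjusted p = 0.00215), the TNF-induced gene Tnfaip2 (0.77, 0.00405) and the adhesion molecule Icam1 (0.52, 0.0378). Chosen after their values were seen, the cytokine gene Il6 changed by 1.91 (0.000811) and the inducible nitric oxide synthase gene Nos2 by 1.09 (0.00194), both with the block. The list mean of exoNOD replicate 1 lay 0.20 above the mean of the 3 controls of its slide and 0.50 above control replicate 1. It lay below control replicate 3 (−1.47 against −1.19). The other pairs differed by 0.77 and 0.32.

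Complement and acute phase genes rose as a list (mean 0.64, 11 of 11 higher, camera adjusted p = 0.00268; adjusted p = 0.481 with an estimated correlation). With the replicate block 6 rose and 5 did not pass, among the former the complement proteases C1ra (log2 change 1.03, adjusted p = 0.00274) and C1s1 (0.79, 0.0118) and the ceruloplasmin gene Cp (0.67, 0.0101). Over all genes 0 members passed without the block, and 0 adjusted over the list alone. For exoNOD replicate 1 the list mean lay 0.26 above the mean of the 3 controls and 0.59 above control replicate 1. It lay below control replicate 3 (−0.50 against −0.30).

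Interferon-stimulated genes rose as a list by a smaller mean (0.20, 27 of 33 higher, camera adjusted p = 0.0419; adjusted p = 0.726 with an estimated correlation). Once the replicate block was added, 5 rose and 28 did not pass. Those that rose included the antiviral genes Ifit2 (log2 change 1.09, adjusted p = 0.00226), Isg15 (0.76, 0.00638) and Ifit1 (0.38, 0.0358). Over all genes 0 passed without the block and 2 passed adjusted over the list alone. The mean of exoNOD replicate 1 lay 0.17 above the 3 controls, and the pairs differed by 0.39, −0.022 and 0.23. The call of the list was lost without control replicate 1 (0.506), exoNOD replicate 1 (0.262) or exoNOD replicate 3 (0.153) and after scaling by the median (0.130), and with normexp background correction (0.683), where the mean was 0.041 and the median change of all genes 0.35. For the MHC class I antigen presentation genes, which display peptides to T lymphocytes, 0 of 14 members passed in either fit, 0 adjusted over the list alone, and B2m changed by 0.10 (adjusted p = 0.681); the list had a mean of 0.024 and camera ranked it downward (0.770), but upward after quantile normalization (0.624) and in the authors' values (0.664).

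Genes of hypoxia and glycolysis rose together (mean 0.49, 24 of 25 higher, camera adjusted p = 0.000342; adjusted p = 0.481 with an estimated correlation). Under the replicate block 10 rose and 15 did not pass. The examples were hexokinase Hk2 (log2 change 1.04, adjusted p = 0.000598), lactate dehydrogenase Ldha (0.98, 0.000507), the phosphofructokinase gene Pfkp (0.83, 0.00194) and the hypoxia-induced prolyl hydroxylase Egln3 (1.72, 0.00159). Without the block 0 passed over all genes and 2 adjusted over the list alone. On slide 1 the mean of exoNOD replicate 1 lay 0.63 above the 3 controls and 0.54 above control replicate 1. Without exoNOD replicate 1 the list had an adjusted p of 0.0504.

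Cell cycle genes rose as a list (mean 0.33, 26 of 28 higher, camera adjusted p = 0.0111; adjusted p = 0.726 with an estimated correlation). In the fit with the replicate block 9 rose and 19 did not pass, among the former the ribonucleotide reductase gene Rrm2 (log2 change 0.55, adjusted p = 0.0159), the mitotic kinase Aurkb (1.01, 0.0241) and the cyclin gene Ccne1 (0.35, 0.0439). Without the block 0 members passed over all genes and 0 adjusted over the list alone. The mean of exoNOD replicate 1 lay 0.62 above the 3 controls, but 0.11 above control replicate 1. The call was lost without control replicate 2 (0.131), control replicate 3 (0.327) or exoNOD replicate 1 (0.645), and with array weights (0.138).

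Beta cell identity genes fell as a list (mean −0.27, 27 of 30 lower, camera adjusted p = 1.2e-07; adjusted p = 0.438 with an estimated correlation). With the replicate block 13 fell and 17 did not pass. Those that fell included the transcription factors Nkx2-2 (log2 change −0.42, adjusted p = 0.0122) and Mafa (−0.30, 0.043) and Pcsk1n, an inhibitor of prohormone convertase (−0.49, 0.0159). Chosen after their values were seen, the glucose transporter gene Slc2a2 fell by 0.83 (0.000672) and the beta cell peptide gene Ucn3 by 0.73 (0.00194) with the block. Without the block 0 passed over all genes and 2 adjusted over the list alone. Relative to the 3 controls of its slide the mean change in exoNOD replicate 1 was −0.093, and −0.23 relative to control replicate 1. Most lists of markers of non-endocrine cells had positive means, 0.28 for fibroblasts, 0.46 for T lymphocytes, 0.50 for B lymphocytes, 0.42 for acinar cells, 0.31 for duct cells and 0.23 for Schwann cells and neurons, against −0.0067 for macrophages and −0.17 for endothelial cells, and alpha, delta and PP cell markers had −0.13; the part that a changed share of beta cells may have in the fall was not separated.

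Stimulus-secretion coupling genes, which link glucose to hormone release, also fell as a list (mean −0.11, 21 of 26 lower, camera adjusted p = 0.000631; adjusted p = 0.349 with an estimated correlation). Once the replicate block was added, 3 fell and 23 did not pass. The exocytosis protein Snap25 (log2 change −0.40, adjusted p = 0.0156) fell with the block, while the sulfonylurea receptor Abcc8 changed by −0.29 (0.097). Relative to the 3 controls the mean change in exoNOD replicate 1 was −0.15, and −0.12 relative to control replicate 1. Alpha, delta and PP cell markers fell as a list (mean −0.13, 13 of 16 lower, camera adjusted p = 0.00719; adjusted p = 0.438 with an estimated correlation). With the block 2 fell, among them Pyy, which encodes peptide YY (−0.40, 0.0444), and 14 did not pass. This list had an adjusted p of 0.0931 after quantile normalization and 0.106 in the authors' values. Its mean change in exoNOD replicate 1 was −0.13 relative to the 3 controls and −0.079 relative to control replicate 1, and its median change lay at percentile 8.36 of 10000 random lists of equal brightness. In neither of these lists did a member pass without the block, with 0 adjusted over the list alone.

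Beta cell disallowed genes, which beta cells normally keep low, rose as a list (mean 0.33, 13 of 14 higher, camera adjusted p = 0.012; adjusted p = 0.438 with an estimated correlation). Under the replicate block 3 rose, 1 fell and 10 did not pass. Those that rose were Ldha, the growth factor receptor gene Pdgfra (log2 change 1.23, adjusted p = 0.013) and the ornithine aminotransferase gene Oat (0.53, 0.0135). Fibroblasts also express Pdgfra. The fall, named after its value was seen, was that of the chemokine gene Cxcl12 (−0.68, 0.0166). Without the block 0 passed over all genes and 3 adjusted over the list alone. In exoNOD replicate 1 the mean lay 0.23 above the 3 controls and 0.19 above control replicate 1.

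**Figure D3:**
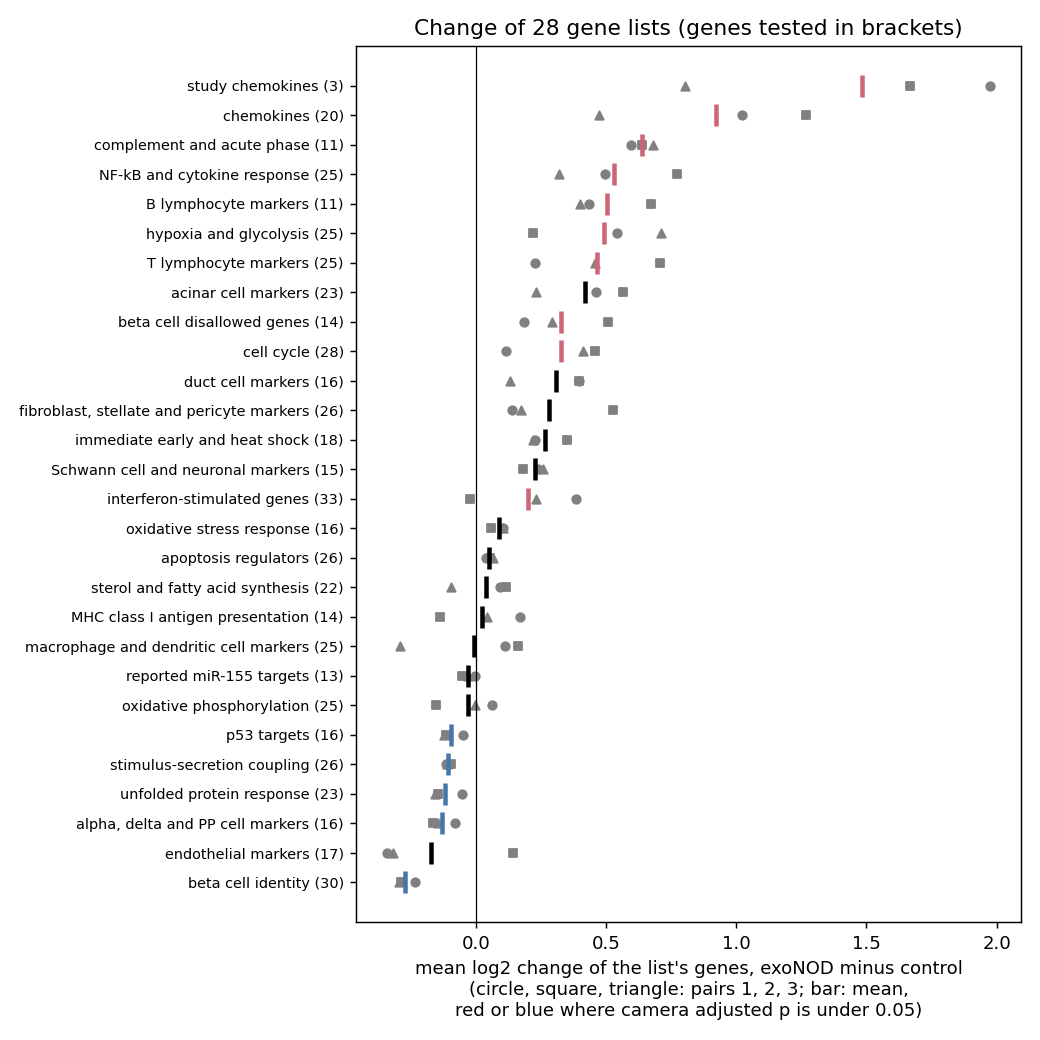
Mean log2 change, exoNOD minus control, of the tested genes of each of 28 lists (horizontal axis), with grey points for the 3 pairs and a bar for the mean, red or blue where camera's adjusted p is under 0.05 and black otherwise. The study chemokines (1.48) and the chemokines (0.92) have the highest means and beta cell identity (−0.27) the lowest.

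Unfolded protein response genes fell as a list (mean −0.12, 21 of 23 lower, camera adjusted p = 0.00464; adjusted p = 0.438 with an estimated correlation). In the fit with the replicate block 1 rose, the stress factor Atf3 (log2 change 0.41, adjusted p = 0.0388), 2 fell, among them Chac1 (−0.40, 0.0245), and 20 did not pass. The list's call ended after quantile normalization (0.0513), and its mean change in exoNOD replicate 1 was −0.046 relative to the 3 controls and −0.053 relative to control replicate 1. Targets of p53 fell as a list (mean −0.097, 12 of 16 lower, camera adjusted p = 0.0121; adjusted p = 0.473 with an estimated correlation); with the block 1 fell, Sesn1 (−0.33, 0.0463), and 15 did not pass. This list had a mean change of −0.13 in exoNOD replicate 1 relative to the 3 controls and of −0.052 relative to control replicate 1, and an adjusted p of 0.0931 after quantile normalization, 0.0923 in the authors' values, 0.113 without control replicate 2 and 0.0555 without exoNOD replicate 1, and its median change lay at percentile 11.4 of random lists of equal brightness. Adjusted over the list alone 0 members of either list passed.

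Apoptosis regulators did not pass as a list (camera adjusted p = 0.671, ranked downward, with a mean of 0.051 and a median of −0.0095). With the replicate block 3 rose, 1 fell and 22 did not pass. The inflammatory caspases Casp1 (log2 change 0.59, adjusted p = 0.00698) and Casp4 (0.83, 0.00304) and the death receptor gene Tnfrsf10b (0.53, 0.038) rose. Oxidative stress response genes did not pass (0.770, mean 0.088; ranked downward, but upward after quantile normalization, 0.578, and in the authors' values, 0.572). With the block the haem oxygenase gene Hmox1 rose (0.61, 0.00235), the catalase gene Cat fell (−0.47, 0.00619) and 14 did not pass. Immediate early and heat shock genes had an adjusted p of 0.144, and 0.0212 with the block (adjusted p = 0.435 with an estimated correlation), where 4 rose, among them Egr2 (1.45, 0.00521) and Fos (0.60, 0.0349), and 14 did not pass. Sterol and fatty acid synthesis (0.599, mean 0.037, ranked downward) and oxidative phosphorylation (0.0644, mean −0.033) did not pass, and 0 of 22 and 0 of 25 members passed in either fit. Reported targets of miR-155, a microRNA of activated lymphocytes, did not pass (0.144, mean −0.030). With the block 1 of 13 rose, Socs1 (0.55, 0.016), 1 fell, Jarid2 (−0.33, 0.0362), and 11 did not pass. Without the block 1 oxidative stress gene, 1 immediate early or heat shock gene and 0 genes of the other 4 of these lists passed adjusted over the list alone.

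Markers of T lymphocytes rose as a list (mean 0.46, 23 of 25 higher, camera adjusted p = 0.000117; adjusted p = 0.475 with an estimated correlation). Once the replicate block was added, 5 rose and 20 did not pass. Ifng, the interferon gamma gene, was above background on 3 exoNOD arrays and 0 control arrays and at least 2.85-fold higher (adjusted p = 0.075, 0.00224 with the block). Gzmb, which encodes granzyme B, changed by 0.86 (0.204, 0.0672 with the block; above background on 2 control arrays). In exoNOD replicate 1 the mean lay 0.21 above the 3 controls and 0.23 above control replicate 1, and the other pairs differed by 0.71 and 0.46. The median change of the list lay at percentile 99.99 of random lists of equal brightness. B lymphocyte markers rose as a list (mean 0.50, 10 of 11 higher, camera adjusted p = 0.00925; adjusted p = 0.438 with an estimated correlation). With the block 3 rose, among them Ms4a1, which encodes CD20 (at least 3.15-fold, 0.00858), and Cd79b (1.05, 0.00478), and 8 did not pass. The median change of this dim list, 0.29, lay at percentile 78.7 of random lists of equal brightness. Its mean in exoNOD replicate 1 lay 0.48 above the 3 controls and 0.43 above control replicate 1. Without the block 1 T lymphocyte and 4 B lymphocyte markers passed adjusted over the list alone, and 0 over all genes.

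Macrophage and dendritic cell markers moved apart. Under the replicate block the mannose receptor gene Mrc1 rose (log2 change 2.20, adjusted p = 0.00175; above background on 1 control array), and Itgam (−0.50, 0.00891), Adgre1 (−0.87, 0.0157) and Aif1 (−0.62, 0.00652) fell, while 21 did not pass. The list did not pass (mean −0.0067, camera adjusted p = 0.0953). Its mean change in exoNOD replicate 1 was −0.14 relative to the 3 controls, but 0.11 relative to control replicate 1. Fibroblast, stellate and pericyte markers had a mean of 0.28 (0.0641) and rose with the replicate block (0.00871; adjusted p = 0.702 with an estimated correlation), where 7 of 26 rose, among them Timp1 (1.54, 0.000131), Vim (0.73, 0.00265) and Fbln1 (0.74, 0.0407). Endothelial markers had a mean of −0.17 (0.0644) with 9 of 17 lower, and ranked downward with the replicate block (0.0253; adjusted p = 0.650 with an estimated correlation), but the pairs differed by −0.34, 0.14 and −0.32. With that block Robo4 (−0.81, 0.00562) and Ptprb (−0.84, 0.00625) were among 6 falls, Plvap rose (0.43, 0.021) and 10 did not pass. Relative to the 3 controls exoNOD replicate 1 had a mean change of 0.045 for the fibroblast and −0.071 for the endothelial list. Without the block 2 macrophage and dendritic cell, 3 fibroblast and 8 endothelial markers passed adjusted over the list alone, and 0 over all genes.

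Acinar, duct and nerve markers did not pass as lists with camera in the fit without a block. Acinar cell markers had a mean of 0.42 (camera adjusted p = 0.0644). In the fit with the replicate block 4 rose, among them Reg3b (log2 change 3.12, adjusted p = 0.00403; above background on 1 control array), a secreted lectin induced in pancreatitis, and Cpa1 (0.64, 0.0364), while 1 fell and 18 did not pass; the fall, named after its value was seen, was that of Bhlha15 (−0.37, 0.0266). Duct cell markers had a mean of 0.31 (0.599), and with the block the chloride channel Cftr (0.82, 0.000946), Spp1, which encodes osteopontin (1.56, 0.00292), and Car2 (1.95, 0.0141; above background on 1 control array) rose and 13 did not pass. Schwann cell and neuronal markers had a mean of 0.23 (0.065), and with the block 2 rose, among them Elavl4 (0.46, 0.00982), and 13 did not pass. This list passed upward by fry with the replicate block (0.0215), but not with camera in that fit (0.0656; adjusted p = 0.435 with an estimated correlation), and its mean in exoNOD replicate 1 lay 0.19 above the 3 controls. Without the block 1 acinar, 0 duct and 1 nerve marker passed adjusted over the list alone, and 0 over all genes.

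With the preset correlation 10 lists rose and 5 fell, and with the replicate block 12 rose and 6 fell. With an estimated correlation 0 lists passed in either fit. By fry, which tests whether a list's genes move on balance in 1 direction, 0 lists passed. With the block 2 rose, complement and acute phase and the Schwann cell and neuronal markers, and 2 fell, beta cell identity and stimulus-secretion coupling. Camera with slide as a block, which rests on exoNOD replicate 1 alone, gave 9 rises and 5 falls. These left out NF-kB (adjusted p = 0.153), complement (0.176) and the unfolded protein response (0.349), and included the nerve and the macrophage markers.

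**Figure D4:**
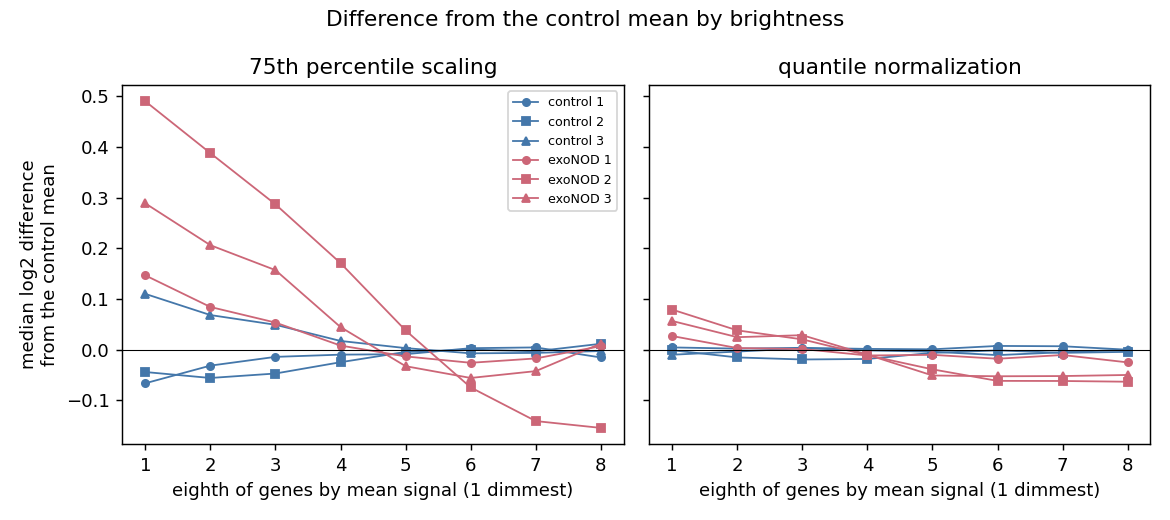
Median log2 difference of each array from the control mean (vertical axis) in eighths of the tested genes ordered by mean signal (horizontal axis, 1 dimmest), after scaling by the 75th percentile (left) and after quantile normalization (right), blue for control and red for exoNOD arrays. In the dimmest eighth the exoNOD arrays lie at 0.15, 0.49 and 0.29 after scaling by the 75th percentile and the controls between −0.067 and 0.11; the median change of that eighth is 0.31 on the left and 0.056 on the right.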

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

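The alternatives within slide 1, those combining 2 choices and the 2 further normexp fits were chosen after seeing the data. The count of 27 genes (26 rose, 1 fell) became 2256 (1784 and 472) with the replicate block, 157 (118 and 39) with normexp, 13 (12 rose) with median scaling, 307 (265 and 42) with array weights, 324 (274 and 50) at an adjusted p under 0.1 and 1877 (1799 and 78) at an unadjusted p with 1.5-fold. Falls numbered 12 after quantile normalization and 13 in the authors' values. In limma 0 genes (0 and 0) passed with no filter (4637 at an unadjusted p under 0.05), without trend (4357), with slide as a block (929), within slide 1 (1143), and with the RMA-75 estimate without (123) or with the replicate block (139). Normexp without the outlying backgrounds gave 14 (13 rose), and 1399 (1055 and 344) with the replicate block. The block gave 1196 (819 and 377) with quantile normalization, 1257 (864 and 393) with the authors' values, 4162 (3440 and 722) without pair 1, 431 (357 and 74) without pair 2 and 1729 (1484 and 245) without pair 3. Leaving out a replicate number or array gave 0 to 1269 genes, 0 to 1210 rises and 0 to 59 falls. Lists that fell, 5 as reported, numbered 2 after quantile normalization, 3 in the authors' values, 8 with no filter and 8 with the replicate block without pair 1. With an estimated correlation or fry 0 rose and 0 fell. The RMA-75 estimate gave 5 rising and 10 falling, and 4 and 8 with the block. The study chemokines (1.48) no longer passed with an estimated correlation (1.48, adjusted p = 0.475), with fry (1.48, 0.257) or within slide 1 (1.25, 0.0734), and leaving out a replicate number or array gave means from 1.12 to 2.01 (adjusted p = 0.0855 without replicate 1). Ppy passed with the block after quantile normalization and in the authors' values (−0.39 in each).

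Normexp gave exoNOD replicate 3 a background mean of −731, and 8.42 once its 6 spots with a local background over 100 were given the array's median background. Control replicate 2 had −19.2, and 7.20 once its 2 such spots were treated likewise. The lowest correlation of equal replicate numbers, 0.280 as reported, was −0.362 with normexp and −0.713 with the RMA-75 estimate, and the first component held 94.0% and 90.1% of the variance. Camera ranked the interferon list downward with normexp, where its mean stayed positive (0.041) and the median change of all genes rose from 0.035 to 0.35. With normexp 7 lists rose and 7 fell. Besides the interferon list, 2 lists no longer passed and 2 newly passed. With the RMA-75 estimate the means turned negative for interferon (−0.89, with or without the replicate block) and for hypoxia and glycolysis (−0.48, in both), the study chemokines had a mean of 0.46, and the hormone genes changed by −3.00 to −2.49, among them Ins2 (−2.98 against −0.07) and Gcg (−2.98 against −0.10); with normexp they changed by −0.59 to −0.22. None of these hormone changes passed. Oxidative phosphorylation turned upward within slide 1 (0.088), and MHC class I genes were ranked upward with the replicate block without pair 2 (0.11). The cause of changes other than those with normexp was not tested. Over the 27 lists other than the study chemokines and all alternatives, 685 values kept direction and side of the threshold, 50 passed in neither setting and changed direction, 79 newly passed, 70 no longer passed and 7 that passed in a setting turned. For named genes 108 passed in neither and changed sign, 886 newly passed, 152 no longer passed and the others kept both. The named genes of this tally include those chosen after their values were seen. Many of these were chosen by their p or change with the replicate block, so their passing with the block follows from that choice. For hormone genes 169 kept both, 15 passed in neither and changed sign and 2 newly passed. Genes with microRNA seed sites and the longer site were not run. Genes near background limit the fold changes of 111 genes to bounds.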

Other observations

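The tests of explanations and the splits of the arrays in this part were all chosen after the results they examine were seen, as were the genes of the next paragraph.

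Among genes with an established symbol that passed with the replicate block and had the same sign in all 3 pairs, the 12 greatest estimated rises included the eosinophil attractants Ccl11 (log2 change 3.76, limma adjusted p = 0.000619 with the block) and Ccl24 (2.87, 0.00079), the platelet chemokine Pf4 (2.94, 6.58e-06), the fibrinogen gene Fgg (3.41, 2.44e-05), the oxidised lipoprotein receptor gene Olr1 (2.86, 0.00182) and the BMP antagonist Grem1 (2.60, 0.00274). Of these, Ccl11, Olr1 and Grem1 were above background on 1 control array and Ccl24 on 2, so the sizes of their rises rest on controls near background. Ear1, an eosinophil-associated ribonuclease, was above background on 3 exoNOD arrays and 0 control arrays and at least 3.73-fold higher (0.00353). The greatest falls included the agrin receptor gene Lrp4 (−1.53, 0.00288), Slamf9 (−1.25, 0.00079), the extracellular matrix genes Aspn (−1.21, 0.0238; above background on 2 exoNOD arrays) and Lama1 (−1.18, 0.00319), the fractalkine receptor gene Cx3cr1 (−1.11, 0.00479) and the endothelial receptor gene Cd93 (−1.11, 0.00523). In exoNOD replicate 1 against the controls of its slide, Ccl11 differed by 3.22, Pf4 by 3.19, Lrp4 by −1.24 and Cx3cr1 by −1.26.

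The 11 falls next in order of p after Apoe, from Fgf23 to Fam107a, moved alike, by log2 changes between −0.55 and −0.68 that passed with the replicate block, at mean levels between 1.65 and 3.57. Within 0.1 (root mean square over the 6 arrays) of their mean profile lay 38 genes. The 11 falls were picked by low p and equal sign in all pairs, so their likeness may follow from that choice. Genes near other profiles were not counted for comparison.

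More genes rose than fell, 79.7% of those at an unadjusted p under 0.05. A brightness-dependent shift that 1 factor per array leaves in place may account for much of the excess, since after quantile normalization 57.8% had risen. The second slide is also open: the dimmest eighth of genes in exoNOD replicate 1, on the slide of the controls, had a median change of 0.147 against 0.110 in the highest control, too close to decide. A true excess of rises after exosome treatment stays open and untested, since quantile normalization could remove it too. The real split gave 27 genes, with the highest of the other splits at 0 (1 of 10 splits as large), and with the replicate block 2256, with the highest of the others that part all 3 pairs at 0 (1 of 4); these splits are too few for a share under 0.05.

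The chemokine and NF-kB lists rose. A brightness-dependent shift as the whole cause is argued against by their camera adjusted p after quantile normalization, 0.000635 and 0.000119. Over all settings, by camera or fry, these ran from 2.21e-33 to 0.438 and from 4.8e-13 to 0.558, highest with an estimated correlation. More macrophages and dendritic cells as a whole are argued against by the upper quartile of their markers, 0.045, below the lower of the list medians, 0.37. Those markers moved apart, Mrc1 up and Itgam, Adgre1 and Aif1 down with the replicate block. The quartile therefore cannot speak for a part of these cells. More fibroblast-like cells could contribute, with an upper quartile of 0.44 for their markers. The second slide stays open by the values of exoNOD replicate 1. There the chemokine list lay 0.687 and the NF-kB list 0.200 above the mean of the controls of its slide, against control SDs of 0.55 and 0.42. In the NF-kB list control replicate 3 lay above exoNOD replicate 1. The pair on that slide differed by 1.02 and 0.50, near the list means of 0.92 and 0.53, but 1 pair has no spread to decide by. A response to the exosomes, the difference the design names, is consistent with these values and was not tested apart from the slide. The real split gave 15 lists and the other splits between 6 and 13 (1 of 10 as large), too few splits for a share under 0.05. With the preset correlation many lists thus passed also in splits that mix control and exoNOD arrays.

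T lymphocyte markers rose in exoNOD cells, and the exosomes came from T lymphocytes; 22 of the 25 tested members were above background on all 3 control arrays and 2 belong to another list too. A brightness-dependent shift as the whole cause is argued against by an adjusted p of 0.000299 after quantile normalization (over all settings 1.02e-05 to 0.475, highest with an estimated correlation). The second slide stays open, since in exoNOD replicate 1 the list lay 0.205 above the controls of its slide, against a control SD of 0.11, and the pair on that slide differed by 0.23 where the others differed by 0.71 and 0.46. T lymphocyte RNA in the exosome preparations may contribute but was not decided. Cd3d, Cd3g, Cd247, Tcf7 and Lef1, abundant in T lymphocytes, were above background in 6 of 15 readings on exoNOD arrays and in 1 on controls, with Cd3g in 0. All of them had missed the background filter, so none could be above background on all 3 exoNOD arrays. A count near 15 was thus excluded in advance, and this count decides nothing here. Cd3e changed by −0.18 at a control level of 3.52, while Cd3d and Cd3g were above background on 0 control arrays. Whether the Cd3e probe reads T lymphocyte RNA was not tested, so its change decides nothing here. A change in lymphocytes carried over with the islets, or in gene expression of the islet cells themselves, stays open and untested.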
